A study of Gallus gallus with 54 samples.

How the data were processed

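Messenger RNA of heart, breast muscle and spleen was sequenced from indigenous Ethiopian chickens (Gallus gallus) of 2 origins. Per the labels, one origin was a high altitude breed not adapted to heat and the other a low altitude breed adapted to heat. The 54 libraries made 6 groups of 9, and each group was read from the letter, number and tissue in a library's title. The labels reuse the codes H1 to H9 and L1 to L9 in the 3 tissues but do not say that a code is one bird, and they give neither sex nor batch, so the p-values below measure the spread between libraries of a group.

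The deposited files held whole-number counts per gene, 1 file per library, with no normalization visible in the values. Per the submitters' processing notes, FastQC, HISAT2 2.0.4, featureCounts, Cufflinks, Cuffdiff and the chicken build galGal4 were used, without the role or order of each. Per the labels' protocols, libraries were made with a stranded TruSeq mRNA kit; the strand setting of the counting is not given in the sources used here, so reads of overlapping and antisense genes, and of near-identical paralogs, were taken as uncertain. Each file listed 24881 gene identifiers, of which 21515 had a count in at least 1 library, and no row lacked a gene. Of the identifiers, 0 matched the reference table of 25635 genes (assembly GRCg7b), and the files do not pair them with symbols. Gene symbols, chromosomes and positions were therefore not used here. The 30 lists of genes fixed in advance, among them the markers of other cell types, could not be tested, and neither could the W-linked covariate or the removal of Z and W genes.

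Counts were tested with edgeR 4.0.16 in R 4.3.3. Within each tissue, 9 low altitude libraries were set against 9 high altitude libraries after TMM scaling and edgeR's default filter on low counts, with the robust quasi-likelihood test, and genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as past the threshold. Log2 fold changes are low over high altitude, and their standard errors (SE) are the fold change divided by the root of the quasi-likelihood F. Levels are log2 CPM (counts scaled to library size) with a prior count of 2. Differences between tissues were tested as the interaction of tissue and altitude over the 36 libraries of each pair of tissues. The number of genes past the threshold with one sign in all 3 tissues was counted, and the Pearson correlation of fold changes across genes was computed for each pair of tissues. Single values per library were compared by two-sided exact permutation tests. The rule for named genes asked for genes with symbols: those past the threshold with the largest changes or else those with the smallest p per direction, members of the fixed lists, 4 stress genes, and the genes with the smallest p of each interaction. It could not be followed without symbols; in its place, and chosen after the data were seen, the 2 identifiers per direction and tissue with the smallest p and an average log2 CPM of at least 1 were named, and the 1 gene past the threshold, which lies under that level, was named after its values were seen.

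Genes selective for a tissue were taken, after the data were seen, in place of the fixed lists: a mean of at least 20 CPM and at least 32 times the mean of either other tissue, with both altitudes weighing equally. They numbered 71 for heart, 92 for breast muscle and 308 for spleen. Their shares of the counts were compared, and limma 3.58.1 camera tested each group with a preset correlation of 0.01 and again with an estimated one, adjusted over the 4 groups tested in a tissue; the fourth was a group of genes that varied together between codes. For that group, log2 CPM was centred within altitude, and genes with a correlation above 0.6 over the shared codes in every pair of tissues were clustered by average linkage at a height of 0.5.

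The gene tests, the interaction test and the search for genes that vary together were tested on simulated counts made from the real means, dispersions and library sizes. For the gene tests 200 genes were changed. For the interactions of heart and breast muscle, heart and spleen, and breast muscle and spleen, 194, 170 and 151 were changed. At a log2 change of 2, edgeR recovered 91% of changed genes in heart (11748 genes tested), 89% in breast muscle (9979) and 93% in spleen (12984); at a log2 change of 1 it recovered 45%, 53% and 60%. It called 3, 5 and 7 unchanged genes, against 19, 15 and 22 by DESeq2, and 0 where nothing was changed. In these gene tests each library was drawn independently, with no library made to stand apart. The numbers therefore do not show how often false calls arise in the real libraries. At a log2 change of 2 in 1 tissue, the interaction test recovered 77.6% for heart and breast muscle, 88.1% for heart and spleen and 83.3% for breast muscle and spleen. Of 100 genes made to vary together, 99 were found, with 0 others. Their shared change was drawn with a larger SD than the mean level of the real group had within an altitude, 0.680 to 1.31 log2. Recovery at the real size was therefore not shown.

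Alternatives fixed before the data were examined were RLE and upper-quartile factors, no filter, a filter of at least 1 CPM in 9 libraries, DESeq2 1.42.0, limma-voom, a threshold of 2-fold, removal of the 20 most abundant genes, the replicate number as a block, up to 3 surrogate variables from sva 3.50.0, and leaving out each library. Those added after seeing the data were DESeq2 without outlier replacement, voom with quality weights, removal of libraries whose median Spearman correlation with their tissue was under 0.9, and a covariate from the genes that varied together. This covariate was the mean level of that group of genes in the other tissues. Chance was assessed by 100 splits of the codes, the real one included, with a code kept together over tissues.

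Total counts ran from 9.31 to 15.2 M (mega) per library. No 2 libraries of a group agreed within sampling noise: the lowest chi-square per degree of freedom over the 216 pairs was 19.5. Figures were drawn with matplotlib 3.10.9.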

Results

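Heart, breast muscle and spleen were profiled in 9 libraries per altitude, 54 libraries in 6 groups. Heart libraries held 12.4 to 15.2 M (mega) counts, breast muscle libraries 9.31 to 13.1 M and spleen libraries 11.6 to 14.3 M. In heart the totals were higher at low altitude, with 14.6 ± 0.668 M (SD, n = 9) against 13.5 ± 0.873 M (n = 9; exact permutation p = 0.0109). In breast muscle they were 12.0 ± 0.671 against 11.2 ± 1.49 M (p = 0.155, exact permutation test, n = 9 each), and in spleen 13.6 ± 0.656 against 12.8 ± 0.932 M (p = 0.0650, exact permutation test, n = 9 each).

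The first question was whether each library carried the genes of its labelled tissue. All 54 libraries correlated best with another library of their own tissue: over the genes that passed the filter across all 54 libraries, the lowest Spearman correlation within a tissue was 0.882 and the highest between tissues 0.829. The 71 heart-selective genes held 8.88% ± 1.67 of the counts in high altitude hearts (SD, n = 9) and at most 0.0345% in any breast muscle library. The 92 breast muscle-selective genes held 14.7% ± 6.78 of the counts in high altitude breast muscle and 21.4% ± 3.58 in low altitude breast muscle (n = 9 each), and at most 0.249% in any heart library. The 308 spleen-selective genes held 7.37% ± 0.713 and 7.40% ± 0.834 in high and low altitude spleens (n = 9 each), and at most 0.186% in any heart library. These genes were chosen on the same libraries, so their shares describe the tissues and do not test the labels independently. The plot of shares gives each library's value.

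**Figure D1:**
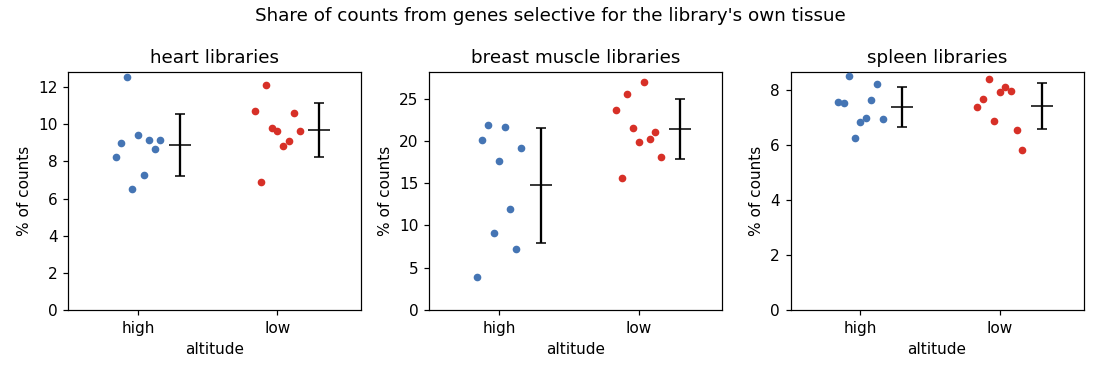
Percent of counts from genes selective for the library's own tissue, one point per library, for high and low altitude; bars give the mean and SD of 9 libraries. Breast muscle at high altitude spans 3.92% to 21.9%, wider than at low altitude (15.6% to 27.0%).

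The heart comparison asked which genes differ between birds of low and high altitude origin. The gene with the smallest p, ENSGALG00000041988, had 7.26 ± 1.32 log2 CPM (SD, n = 9) at high altitude and 5.06 ± 0.78 at low altitude, a log2 fold change of -2.53 (SE 0.48), and was below the high altitude median in 9 of 9 low altitude libraries. ENSGALG00000013818 had a log2 fold change of -1.77 (SE 0.40). In the other direction, ENSGALG00000003015 stood at 1.41 (SE 0.31) and ENSGALG00000033351 at 1.88 (SE 0.43), each above the high altitude median in 9 of 9 low altitude libraries. None of these passed: their edgeR adjusted p were 0.247 for the first and 0.486 for the other 3. Of 11872 genes tested by edgeR's quasi-likelihood test, 0 were past the threshold, and 718 had an unadjusted p under 0.05, where 593.6 are expected with no difference; limma-voom gave 0 and DESeq2 22 genes past the threshold, the 4 named genes among them (DESeq2 adjusted p 6.63e-05 to 0.0133). Without high altitude heart replicate 3, the genes with an unadjusted p under 0.05 numbered 1308, and without high altitude replicate 8, 476; without high altitude replicate 9, 1 gene passed the threshold. The files do not pair these or the identifiers below with gene names.

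For heart-selective genes in heart, no difference between the altitudes held in every test. Of the 71, 49 had a positive and 22 a negative log2 fold change, with a median of 0.13, and 0 passed the gene threshold. Their share of the counts was 9.70% ± 1.45 at low and 8.88% ± 1.67 at high altitude (n = 9 each; exact permutation p = 0.281, adjusted over 9 such tests 0.633). Camera gave an adjusted p of 0.0102, which was lost with an estimated correlation (adjusted p = 0.517). For breast muscle-selective genes in heart (32 of the 92 were tested) the camera adjusted p was 0.894. Their median log2 fold change was 0.03 and their mean -0.25. For spleen-selective genes in heart (183 of the 308 were tested) the camera adjusted p was 0.214.

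In breast muscle 1 gene passed the threshold. More genes than in the other tissues had an edgeR unadjusted p under 0.05, but with voom quality weights heart had 1520 such genes and breast muscle 1457. ENSGALG00000042851, named after its values were seen, was higher at low altitude, by a log2 fold change of 2.10 (SE 0.33, edgeR adjusted p = 0.0333), with 8 to 35 counts per low altitude library and 2 to 11 per high altitude library. It was above the high altitude median in 9 of 9 low altitude libraries. ENSGALG00000038520 had a log2 fold change of 1.79 (SE 0.36), ENSGALG00000016589 one of -1.32 (SE 0.26) and ENSGALG00000028037 one of -4.06 (SE 0.78); the edgeR adjusted p of each was 0.0734. For ENSGALG00000028037 the high altitude libraries ran from 106 to 10342 counts and the low altitude ones from 27 to 144, and the library with 10342 counts stood alone.

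Of the 10120 genes tested in breast muscle, 1838 (18.2%) had an unadjusted p under 0.05 where 506.0 are expected, 656 of them higher and 1182 lower at low altitude, and 204 had an adjusted p under 0.1. The excess of lower genes stayed with RLE and upper-quartile factors, no filter, the strict filter, DESeq2 with or without outlier replacement, without the 20 most abundant genes and in each of the 18 fits that left out 1 library, but not in other settings: limma-voom gave 1023 higher and 821 lower, surrogate variables 1013 and 741, the replicate number as a block 812 and 725, voom with quality weights 786 and 671, the covariate from the co-varying genes 528 and 518, and the fit without the 4 libraries under a correlation of 0.9 gave 618 and 618. The call of ENSGALG00000042851 was kept in 5 of the 18 fits that each left out 1 library, and in 5 of the 11 other settings that tested it, with adjusted p from 3.07e-05 to 0.296. The number of genes past the threshold was 455 without high altitude replicate 3, 55 without high altitude replicate 6, 42 without low altitude replicate 2, 2 without high altitude replicate 4, 1 without low altitude replicate 3 and 0 in the other 13. DESeq2 called 469 genes, limma-voom 0.

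For breast muscle-selective genes in breast muscle, no difference between the altitudes held in every test. Of the 92, 67 had a positive log2 fold change and 25 a negative one, the median was 0.36, and 0 passed the gene threshold. Their share of the counts was 21.4% ± 3.58 at low and 14.7% ± 6.78 at high altitude (n = 9 each; exact permutation p = 0.0197, adjusted over 9 tests 0.177). The camera adjusted p of 2.65e-08 was lost with an estimated correlation (adjusted p = 0.351). The high altitude replicates 1, 4, 7 and 8 held the lowest shares, 3.92%, 9.14%, 12.0% and 7.22%, and also the lowest median Spearman correlations with the tissue's libraries over the genes tested in breast muscle, 0.839 to 0.890. Without these 4 libraries, the share of the breast muscle-selective genes was 21.4% at low and 20.1% at high altitude (exact permutation p = 0.460). In that fit 1236 genes had an unadjusted p under 0.05, 500 of them among the 1838. With the 8-fold in place of the 32-fold minimum the share differed with an exact permutation p of 0.181. At the 32-fold minimum, camera gave 0.0465 for heart-selective genes in breast muscle (12 of the 71 were tested), lost with an estimated correlation (adjusted p = 0.351). At the 8-fold minimum, with 59 genes tested, 39 higher and 20 lower at low altitude, camera gave an adjusted p of 0.000149. With an estimated correlation that became 0.138. For spleen-selective genes at the 32-fold minimum (60 of the 308 were tested) camera gave 0.644. Their median of -0.03 and mean of -0.05 lay on the other side of 0 from the test.

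In spleen no gene passed between the altitudes. ENSGALG00000036403 had the highest of the named log2 fold changes, 3.35 (SE 0.65), with 7 to 114 counts at low and 0 to 11 at high altitude, and ENSGALG00000037876 had 2.24 (SE 0.52). ENSGALG00000004339 and ENSGALG00000003242 stood at -2.22 (SE 0.46) and -2.72 (SE 0.57), both below the high altitude median in 9 of 9 low altitude libraries. Their edgeR adjusted p lay between 0.511 and 0.568. Of 13092 genes tested by edgeR, 0 were past the threshold, and 756 had an unadjusted p under 0.05 against 654.6 expected; limma-voom called 0 and DESeq2 20 genes, the 4 named genes among them (DESeq2 adjusted p 0.000411 to 0.0123).

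Spleen-selective genes held nearly equal shares of the spleen counts at the 2 altitudes, 7.40% ± 0.834 and 7.37% ± 0.713 (n = 9 each; exact permutation p = 0.938). Of the 308, 198 had a positive and 110 a negative log2 fold change, with a median of 0.09, and camera gave an adjusted p of 0.0231, lost with an estimated correlation (adjusted p = 0.401) and with an 8-fold minimum (0.410). For the breast muscle-selective genes in spleen (28 of the 92 were tested) the camera adjusted p was 0.0258. It was lost with an estimated correlation (adjusted p = 0.312) and with an 8-fold minimum (0.239). For the heart-selective genes (17 of the 71 were tested) it was 0.772.

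**Figure D2:**
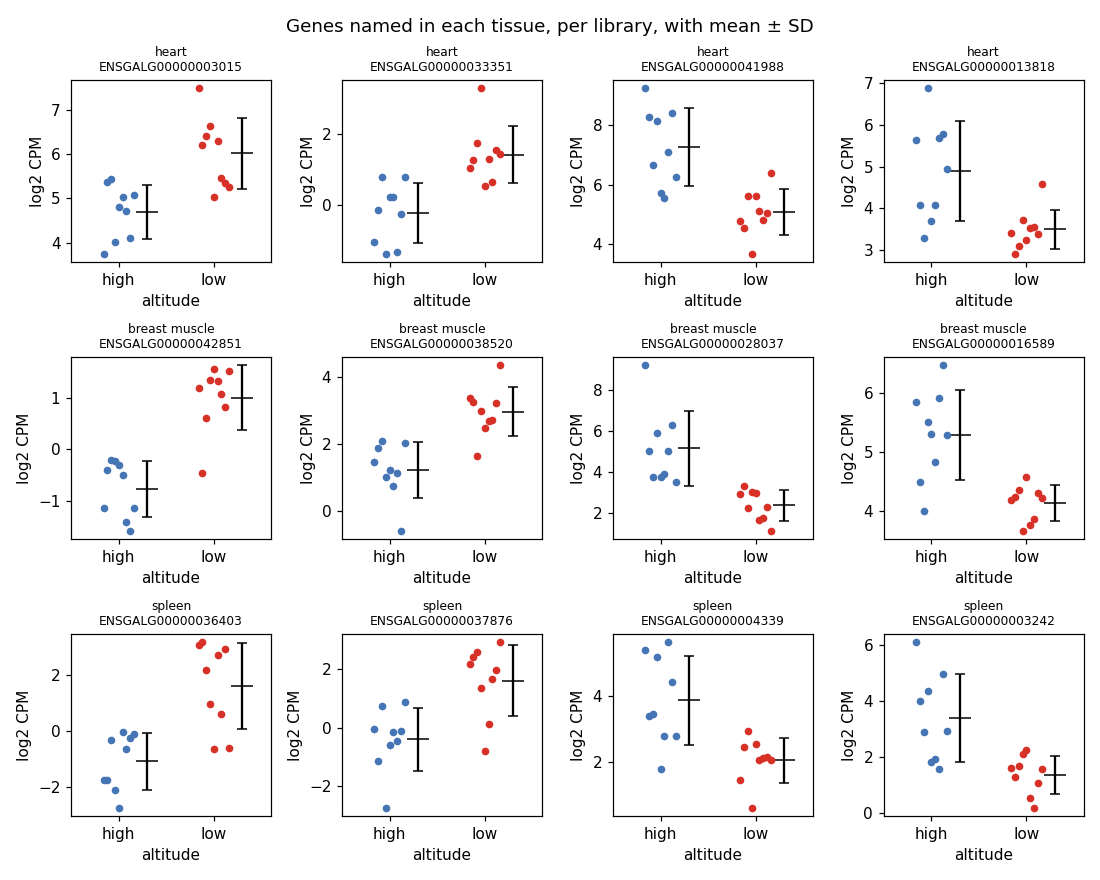
Log2 CPM of the 4 genes named in each tissue, one point per library, at high (blue) and low (red) altitude; bars give the mean and SD of 9 libraries. The gene past the threshold, ENSGALG00000042851 in breast muscle, runs from -0.45 to 1.55 at low and from -1.57 to -0.21 at high altitude.

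**Figure D3:**
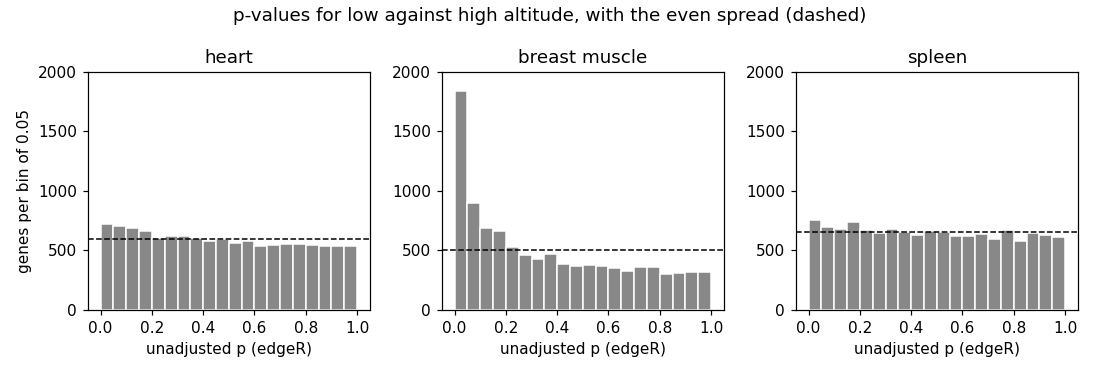
Histogram of unadjusted edgeR p-values for low against high altitude in 20 bins of 0.05; the dashed line is the number per bin with no difference. Breast muscle has 1838 genes in the first bin, against 718 in heart and 756 in spleen.

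The next question was whether the altitude difference itself differed between tissues. For no pair of tissues did a gene pass the edgeR interaction test. Heart and breast muscle had 0 of 12373 genes past the threshold (smallest adjusted p 0.103) and 1330 with an unadjusted p under 0.05, against 618.65 expected. Breast muscle and spleen had 0 of 13597 (smallest adjusted p 0.0575) and 1703, against 679.85 expected. Heart and spleen had 0 of 13918 and 497, against 695.9 expected. Other splits of the codes gave up to 2313 genes at that p for heart and breast muscle and 2141 for breast muscle and spleen. An excess over the expected number therefore does not by itself show that the altitude difference differs between tissues. Limma-voom with the correlation within codes also gave 0 for each pair. ENSGALG00000041988, lower at low altitude in heart, had log2 fold changes of -1.14 (SE 0.35) in breast muscle and -1.13 (SE 0.36) in spleen.

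Over the 9511 genes tested in all 3 tissues, 0 passed with one sign in all 3 by edgeR, limma-voom or DESeq2, and 19 had an unadjusted p under 0.05 with one sign in each; 11 of 100 splits of the codes, the real one included, gave 19 or more (highest other 101). Fold changes correlated across genes, which are not independent replicates, with a Pearson r of 0.222 between heart and breast muscle (9749 genes), 0.353 between heart and spleen (11210 genes) and 0.169 between breast muscle and spleen (9672 genes). In splits of the codes, kept together over tissues, the median r was 0.177, 0.286 and 0.148, and 40, 28 and 42 of 100 splits, the real one included, gave an r as large. The correlations lay within the range of the regrouped codes.

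Libraries also differed within an altitude in a way that followed the code over tissues. A group of 55 genes had a mean level in heart between 3.87 and 7.25 log2 CPM, in breast muscle between 2.33 and 5.14, and in spleen between 5.98 and 8.62. Its mean was highest in codes H4, H7 and L3 in heart, H1, H4 and H7 in breast muscle and H4, H7 and L3 in spleen. Between altitudes the mean over tissues was 4.73 ± 0.78 at low and 5.37 ± 1.07 log2 CPM at high altitude (SD, n = 9; exact permutation p = 0.172, adjusted over the 3 tissues and their mean 0.229). Camera gave the group adjusted p of 6.33e-10 in heart, 2.59e-07 in breast muscle and 1.10e-12 in spleen. Each was lost with an estimated correlation, at an adjusted p of 0.517, 0.351 and 0.312.

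**Figure D4:**
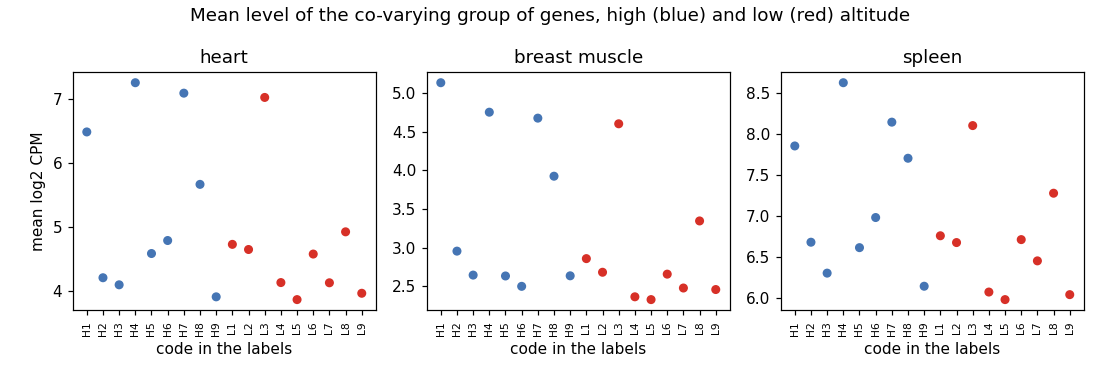
Mean log2 CPM of the group of 55 genes in each library, by code, for heart, breast muscle and spleen; blue is high and red low altitude. H1, H4, H7 and L3 are the 4 highest in each tissue, at 6.48 or more in heart, 4.60 or more in breast muscle and 7.85 or more in spleen.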

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

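The tests that remove the libraries under a correlation of 0.9 or other sets of libraries, the covariate of the co-varying genes, the splits for the 19 genes and the genes behind the shares were chosen after the result was seen. Values per library were tested for a single library far from the others of its group, in 48 sets of 9 values. In 8 sets the gap to the nearest library, as a share of the range, was above Dixon's critical value, where chance gives about 2.4.

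Among the library measures, the share of heart-selective genes in high altitude heart was highest in H3 (12.5%, next 9.41%; gap 0.520 of the range). The mean level of the group of 55 genes that vary together was highest in L3 in low altitude heart (7.02 log2 CPM, next 4.92; gap 0.665) and in low altitude breast muscle (4.60, next 3.35; gap 0.553).

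Among 24 sets for named genes, 5 had such a library. In low altitude heart, ENSGALG00000033351 was highest in L4 (3.30 log2 CPM, next 1.74; gap 0.564) and ENSGALG00000013818 in L9 (4.58, next 3.71; gap 0.519). In high altitude breast muscle, ENSGALG00000038520 was lowest in H8 (-0.58, next 0.76; gap 0.4996) and ENSGALG00000028037 highest in H1 (9.23, next 6.32; gap 0.512). In low altitude breast muscle, the gene past the threshold, ENSGALG00000042851, was lowest in L2 (-0.45, next 0.61; gap 0.531).

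In breast muscle, 3 of 100 splits of the codes, the real one included, gave 1838 or more genes with an unadjusted p under 0.05. The others gave 1842 and 1905 and also kept H1, H4, H7 and H8 on one side. For 1 or more genes past the threshold it was 2 of 100 (highest other 49). Both shares are under 5 of 100, but they are not adjusted over the counts tested, so chance is not excluded. The 1 gene was lost in 13 of 18 fits that left out 1 library. Without the libraries that stand apart in breast muscle, H1, H4, H7 and H8, 1236 genes were left, 500 of them among the 1838. Of the 5 removals of 4 of the other high altitude libraries, 100% left more, 3414 to 3969. Each of these kept the 4 with only 1 other high altitude library, so more genes could be foreseen and the comparison cannot decide. Sets holding 1 of the 4 left a median of 2453.5 and sets holding 2 left 1578.5. The 20 sets holding 3 of the 4 left 648 to 1951, with a median of 1025, under the 1236. The number thus depended on which libraries were left out, but how much of it these 4 carried stays open. Codes H1, H4, H7 and H8 are among the 5 with the highest level of the co-varying genes. A covariate was made for each tissue from the mean level of that group in the other tissues. With it, the genes with an unadjusted p under 0.05 numbered 1046 in breast muscle, 365 in heart (from 718) and 408 in spleen (from 756). With log2 total count as a covariate 1163 genes were left in breast muscle, 63.3% of the 1838. That share settles neither the part of depth nor that of altitude of origin, and both stay open.

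In heart and spleen the counts of genes with an unadjusted p under 0.05 were met or passed in 37 and 35 of 100 splits (highest others 2959 and 2356), and the 19 genes with one sign in all 3 tissues at that p in 11 of 100 (highest other 101), so chance cannot be excluded. Where 0 genes passed by edgeR (heart, spleen, each interaction and the overlap of all 3 tissues), any split meets the count, so the 100 of 100 found carries no information. The highest other counts there were 80 in heart, 422 in spleen, 3, 1 and 26 for the interactions of heart and breast muscle, heart and spleen, and breast muscle and spleen, and 0 for the overlap. The split with 80 genes in heart and 422 in spleen gave 0 in breast muscle. It put H2, H3, H5, H6, H9, L2, L5, L6 and L7 on one side and so H1, H4, H7, H8 and L3 together on the other. The split with the most genes in breast muscle, 49, parted H8 and L3 from H1, H4 and H7. Both were picked as the highest of the splits, so they do not establish a structure of the libraries across altitudes. Having those 5 codes together was not enough for such counts: another split that did so, with H9, L6 and L7 in place of L4, L8 and L9, gave 0 genes past the threshold by edgeR in each tissue, with 1087, 1240 and 967 at an unadjusted p under 0.05 in heart, breast muscle and spleen.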

How the results depend on the processing

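The tests marked here as added, and those on the co-varying genes, were chosen after the data were seen. How many genes were past the threshold depended on the test more than on scaling or filter. RLE and upper-quartile factors kept the counts of 0, 1 and 0 genes in heart, breast muscle and spleen, and the 2-fold threshold kept all 3. DESeq2 called 22, 469 and 20 genes and, without its outlier replacement (added after seeing the data), 12, 462 and 20; limma-voom gave 0 in each tissue. On simulated counts DESeq2 made more false calls than edgeR, but the cause of the gap was not tested. In breast muscle the count went from 1 to 0 with no filter, with the strict filter and without the 20 most abundant genes (in both of which that gene was not tested), with limma-voom, and with the added voom quality weights and covariate from the co-varying genes. It was 6 with surrogate variables and 2 without the 4 libraries under 0.9 (added); the cause was not tested. Leaving out single libraries gave 0 to 455 genes in breast muscle, 0 to 1 in heart and 0 in spleen. The breast muscle gene kept a log2 fold change of 1.81 to 2.14 over 11 alternatives, with adjusted p of 3.07e-05 to 0.296. No named gene changed sign under any of 149 alternative values, but some log2 fold changes shrank: ENSGALG00000028037 from -4.06 to as little as -1.60 (-2.41 with DESeq2), ENSGALG00000013818 from -1.77 to -0.66, ENSGALG00000016589 from -1.32 to -0.72, ENSGALG00000004339 from -2.22 to -1.09, ENSGALG00000003242 from -2.72 to -1.63 and ENSGALG00000041988 from -2.53 to -1.62.

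Whether the numbers H1 to H9 and L1 to L9 pair high with low altitude libraries was not settled. In heart, breast muscle and spleen, libraries of one number had median correlations of 0.189, -0.114 and 0.134 (lowest -0.176, -0.299 and -0.320). Libraries of different numbers had medians of -0.0186, -0.0348 and -0.0123. Of 9 pairs, 3, 3 and 4 correlated best with their own number, a hint from the data, not the design. With the replicate number as a block, edgeR called 0 genes in heart, breast muscle and spleen. Between tissues, libraries of one code correlated with a median r of 0.150, 0.362 and 0.141, but the lowest were 0.0673, 0.000564 and -0.0658, and 5, 11 and 6 of 18 correlated best with their own code, a hint from the data that codes mark birds. Interaction counts stayed at 0 with the code as a block, RLE factors, no filter, voom or without the libraries under 0.9.

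The W-linked covariate, the removal of Z and W genes and all alternatives for the fixed gene lists were not run, because the identifiers could not be matched to symbols. Raising the correlation minimum of the co-varying genes to 0.7 gave 46 genes and lowering it to 0.5 gave 230, against 101 at 0.6. The largest group then held 24 genes, all among the 55, or 64 genes, 37 of them among the 55. With the 8-fold minimum (added), camera adjusted p under the preset correlation went from 0.214 to 0.0138 for spleen-selective genes in heart (0.613 with an estimated correlation), from 0.0231 to 0.410 for those in spleen and from 0.0258 to 0.239 for breast muscle-selective genes in spleen.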

Other observations

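The tests on the co-varying genes were chosen after the data were seen; that of the reassigned codes was chosen after its result was seen, and that of altitude after the co-variation was seen. Over the 9511 genes tested in all 3 tissues, 101 had a correlation above 0.6 between libraries of one code in every pair of tissues, after centring within altitude. The largest cluster held 55 genes, the next 4. The mean level of these 55 genes moved by up to 10.4-fold between codes in heart, 7.01-fold in breast muscle and 6.25-fold in spleen. Single genes moved more. ENSGALG00000026970 ran from 447 to 50106 counts in heart and from 3468 to 50991 in spleen, and ENSGALG00000016400 from 72 to 49583 in heart and 308 to 24031 in spleen. The files do not pair these identifiers with names, so the group's function was not examined.

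Genes picked anew from 2 tissues alone, with a correlation above 0.7, followed the level in the third. They were in part other genes than the 55, with 14 of 49 shared where heart was held out, 36 of 138 for breast muscle and 30 of 48 for spleen. Over 18 codes, Pearson's r was 0.951 for heart held out (Spearman's rho 0.924), 0.891 for breast muscle (rho 0.792) and 0.934 for spleen (rho 0.967). Permutation p were 1e-05, 5e-05 and 1e-05 for r and 1e-05, 0.00017 and 1e-05 for rho, where 1e-05 is the smallest that 100000 resamples can give; adjusted over the 3 they were at most 0.00017. Without the 2 codes farthest from the median, r was 0.943, 0.817 and 0.887. Among the codes below the largest gap, 14, 15 and 14 of them, r was 0.852, 0.730 and 0.942.

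Reassigning codes within altitude gave as many genes in 1 of 100 cases, the real one, which is the smallest share that 100 cases can give. The real codes gave 101 genes, against a highest other of 2 and a median of 0. These values argue against a chance match of codes, but do not exclude it. Cells or RNA of the spleen type would raise spleen-selective genes in step. The larger of the 2 median slopes on the group's level was 0.0667, in heart, against 1.03 for the group itself. These slopes cover 182 of the 308 spleen-selective genes in heart and 59 in breast muscle. The genes were chosen on the same libraries for low levels in heart and breast muscle, so the slopes cannot exclude such cells. Library depth is argued against by Spearman correlations of the group's level with the total count of -0.344 in heart, -0.271 in breast muscle and -0.110 in spleen (size 0.110), all of one sign but the last too small for depth to drive all 3 tissues. A search without centring found 106 genes, 54 of the 55 among them. Reassigning codes within altitude, which keeps a difference between altitudes, left at most 2, or 1.89%. Since few genes differed between the altitudes, a small number could be foreseen, so this search does not decide on altitude. A difference between the altitude means could not have formed the 55 genes, which were chosen after centring within altitude. A hypothesis is that the codes mark birds whose tissues may share a state, such as one that acts throughout the body. Sex and health of the birds were not tested. Batch or sampling shared by a code was not tested and stays open, as does library composition. Codes H1, H4, H7, H8 and L3 had the highest group levels in heart. They also had the lowest shares of heart counts in the 20 most abundant genes, 32.2% to 41.9%. In breast muscle H1 had the lowest share, 13.9%, but L3 the highest among low altitude libraries, 49.4%. In spleen these codes held 13.3% to 15.4%, within the range of the others.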
